A study of Mus musculus with 6 samples.

How the data were processed

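The cranial base of each embryo was taken at E15.5 and kept in RNAlater, a solution that preserves RNA, until genotyping was done, per the labels' protocols. RNA was isolated with a Norgen kit and made into Illumina libraries, per the labels' protocols. One table of 43496 gene entries with Ensembl mouse gene IDs and symbols was deposited, with a value for each library. The values are FPKM, fragments per kilobase scaled to library size, as the authors made them. The submitters' processing notes name Cufflinks, without a version, and the build mm9. The unit itself was inferred from this tool and from the values, since the file headers do not name it. The aligner, the annotation release and the filters are not given in the sources used here. The deposited group means equal the means of the 3 library columns within 0.005. The authors' deposited fold is a signed score, treatment over control where it is 1 or more and minus control over treatment otherwise. The deposited p-value and q-value come from a test that is not given in the sources used here, and 99 stands in place of q in 37016 entries.

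The code 999999999 in place of a value was treated as missing, and the 15 entries with it in any library were left out, among them Myh3, Ryr1, Trp53 and Myh10. There were 59 repeated gene IDs, and each entry was tested on its own. An exact 0 may not mean absence, because the mitochondrial gene mt-Co1 is listed at 0 in all 6 libraries, for a reason that is not given. The level of a gene listed at 0 in any library is therefore given as each library's value, without a mean or a fold. A log2 change of such a gene is printed only where its direction turned with the processing, beside each library's value. No coordinates are given, because the annotation at hand is of another build. The annotation, of GRCm38, was used only for gene types and exon lengths by gene ID, which 15610 of 15710 tested entries had, and for which genes neighbour Memo1.

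Genes with a mean of at least 1 FPKM over all 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with lmFit and eBayes with trend and robust estimates, genotype as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Array weights came from limma's arrayWeights, and the random effect of the title word from duplicateCorrelation with statmod 1.5.0. Gene lists were fixed before the data were examined: 30 lists with 526 members, of which 7 matched no entry, 15 genes stood in more than 1 list, and 29 lists were tested, the list of sex-linked genes serving as a check only. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at the estimated correlation, and with fry, each adjusted over the 29 lists. Genes were named by a rule fixed beforehand. It took Memo1, the 12 largest rises and the 12 largest falls past the threshold without overlap between groups and with at least 2 FPKM in the higher group. Where a direction had fewer than 8 such genes, those with the smallest p filled it to 8, which here gave all 16. It also took up to 4 members per list with the smallest p, of which only some are printed, the sex list and genes that a test of an explanation needed. Col2a1, Col10a1, Ext2, Rpl3-ps1, Gpd1, Gm24864, Gm22486, Pomc, Hoxa2, Rsph1, Sntn, Tppp3 and Foxj1 fell outside the first parts of the rule and were chosen after their values were seen. Besides the sex-linked genes, 1 gene that the rule named was left out of the alternatives, and it is not reported here.

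Replicates are separate embryos by their labels. Titles begin with a word whose meaning is not given in the sources used here. Control 1 shares it with mutant 1, and controls 2 and 3 share it with mutant 3. No other embryo has that of mutant 2. The numbers of the replicates follow accession order and pair no samples. No 2 libraries were copies: at most 0.00639% of tested values above 0 were equal between any 2. Depth was read from low values: where control 1 lay below 0.1 FPKM, the ratio of a library to control 1 gathered at 1 value, the worth of 1 fragment, with 135 to 264 genes within 2% of it. In mutant 1 only 4 genes did so, under the 100 asked for, and its depth is not given. The lowest 5% of its values above 0 reached up to 1.87 FPKM, against 0.0258 to 0.0364 FPKM elsewhere.

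The test was tried on simulated data with the means and spread of these libraries, 200 of 15710 genes changed at a time. The changed genes were all drawn from those above 10 FPKM, so recovery of lower genes was not tried. From all 6 libraries it recovered 0%, 0% and 75.5% of genes changed 1.5-, 2- and 4-fold. With array weights these were 35.5%, 92% and 99%, and without mutant 1 0%, 91.5% and 98.5%. Of 29 simulated lists 1 of 20 genes was moved 1.5-fold and was called, and 0 of the unmoved ones were. Each simulated gene was drawn independently of the others. The 0 calls of unmoved lists thus say nothing about false calls where the genes of a list are correlated. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, upper-quartile, quantile and median-ratio scaling, eBayes without trend or robust estimates, the title word as a fixed block or a random effect, array weights, embryo sex as a covariate, each library left out in turn, and for the lists the estimated correlation, fry and lists without shared members. A filter of 20 FPKM was added after seeing the data. Figures and checks used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.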

Results

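RNA was sequenced from the cranial base, the cartilage plate under the brain, of mouse embryos at E15.5, the stage counted in days of gestation. The series held 3 control embryos and 3 Memo1 mutant embryos of the C57BL/6J strain, 1 library each. The mutants carried an allele of Memo1 that came from ENU (N-ethyl-N-nitrosourea), a chemical mutagen. Memo1 is named for its part in cell motility downstream of ERBB receptors. The comparison asked which genes differ in expression between mutant and control cranial base. Values were FPKM for 43496 gene entries, of which 15710 with a mean of at least 1 FPKM over all libraries were tested.

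The 6 libraries differed in depth. The table held no counts, but the steps between low values set the depth of controls 2 and 3 and mutants 2 and 3 at 80.1%, 93.3%, 116% and 152% of that of control 1. Mutant 1 had no usable steps. It listed 30814 genes at 0, against 19789 to 20596 in the other 5 libraries, and 823 genes above 5 FPKM in all of those were listed at 0 there. Across the tested genes its log2 values correlated with those of the other libraries at r = 0.748 to 0.762, against 0.968 to 0.981 among the other 5. The first principal component, with 86.6% of the variance, set mutant 1 apart, and the second, with 5.41%, had all 3 controls on one side and mutants 2 and 3 on the other. Xist, the RNA of the inactive X chromosome, was 114 FPKM in mutant 3 and at most 0.0942 FPKM in the other 5 embryos. The Y-linked Ddx3y was 0.0224 FPKM in mutant 3 and 15.2 to 17.8 FPKM in the others. By these genes mutant 3 was female and the others were male.

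**Figure D1:**
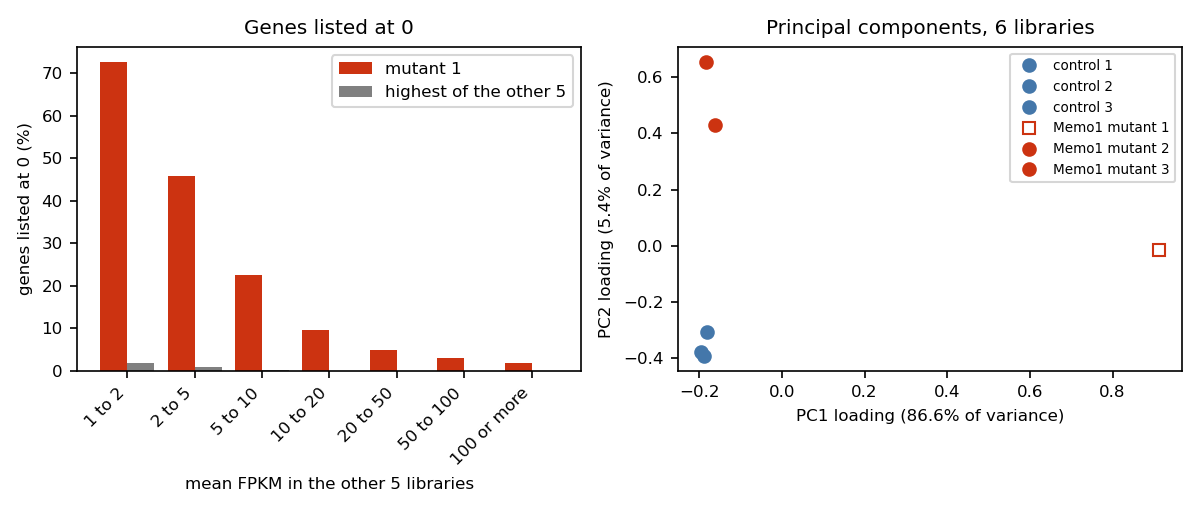
Left, the percent of genes listed at 0 in mutant 1 and the highest percent in any of the other 5 libraries, by the mean FPKM in those 5; right, the loadings of the 6 libraries on the first 2 principal components. At 2 to 5 FPKM, 45.9% of genes were listed at 0 in mutant 1 and at most 0.874% in another library.

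Memo1 itself was present at similar levels in both genotypes. Its mRNA was 21.4 ± 2.04 FPKM in controls and 22.6 ± 2.67 FPKM in mutants (SD, n = 3), with 19.1 to 23.1 FPKM in single controls and 20.1 to 25.4 FPKM in single mutants (log2 change 0.074, SE 0.14, limma adjusted p = 0.802). The sign of this change turned when mutant 1 was left out (log2 change -0.011). Mutations by ENU are mostly base substitutions, which need not change the level of an mRNA, so this level does not check the labels.

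Lists of epithelial, bone and fat cell genes were lower in mutant cranial base, and the list of cartilage genes was higher. These calls used a preset correlation between genes, and none of the 4 lists passed with an estimated correlation (adjusted p = 0.253 for the epithelial, 0.33 for the bone, 0.287 for the fat cell and 0.287 for the cartilage list). Krt5, the keratin of basal epithelial cells, was 90.9 ± 6.17 FPKM in controls and 28.4 ± 1.28 FPKM in mutants (SD, n = 3). Krt19, a keratin of simple epithelia, was 96.9 ± 3.24 FPKM in controls and 48.4 ± 0.924 FPKM in mutants (SD, n = 3). Spp1, the bone matrix protein osteopontin, was 319.9 ± 58.4 FPKM in controls and 94.7 ± 21 FPKM in mutants (SD, n = 3). Matn4, a matrilin of cartilage matrix, was 54.9 ± 7.13 FPKM in controls and 119.9 ± 14.3 FPKM in mutants (SD, n = 3). In the comparison of all 3 mutants with all 3 controls none of these single genes passed. With Benjamini-Hochberg adjustment limma called 0 of 15710 genes at an adjusted p of 0.05, with 805 genes at an unadjusted p under 0.05 where 786 would come by chance. The smallest limma adjusted p was 0.0711, for Krt5. In 3282 genes (20.9%, where chance gives 10%) the 3 mutants did not overlap with the 3 controls.

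That count rested on mutant 1. With array weights, an alternative chosen before the data were examined, a library far from its group counts less. Mutant 1 took a weight of 0.0329 against 1.47 to 2.76 for the other 5 libraries, and limma then called 320 genes, 113 higher and 207 lower in mutants. Without mutant 1 it called 7, 2 higher and 5 lower, and 2666 at an unadjusted p under 0.05. The lower ones were Gpd1, Krt5, Mmp13, Krt19 and Cidec, the higher ones the gene models Gm24864 and Gm22486, and all 7 were among the 320. Gpd1, an enzyme of glycerol phosphate synthesis, was 22.5, 25.1 and 23.3 FPKM in the controls and 0, 2.69 and 1.73 FPKM in mutants 1, 2 and 3. Both gene models were listed at 0 in the 3 controls and mutant 1. In mutants 2 and 3 Gm24864 was 7.6 and 5.84 FPKM and Gm22486 3.27 and 5.03 FPKM. Mutants 2 and 3 were also the deepest libraries with a depth given, at 116% and 152% of control 1. For these gene models depth thus cannot be told apart from genotype. In simulated data of these libraries only genes above 10 FPKM were changed. Of those changed 2-fold limma recovered 0% from all 6 libraries, 92% with array weights and 91.5% without mutant 1. Recovery of lower genes was not tried. Leaving out control 1, 2 or 3 gave 0 genes and 322, 365 and 341 at an unadjusted p under 0.05. Single genes are given here with the weighted adjusted p. For each such gene that the naming rule took, this was the lowest limma adjusted p over the alternatives. Means with SD count mutant 1 in full, as do log2 changes with SE unless marked as weighted. The weighted p tests another estimate, in which mutant 1 counts for little. For Sox9 the log2 change was 0.80 with equal weights and 0.66 weighted. Of the genes given with a weighted p, only Krt5, Krt19, Mmp13 and Cidec also passed without mutant 1. The limma adjusted p there was 0.0506 for Spp1, 0.0568 for Matn4 and 0.0916 for Sox9. Over the alternatives the limma adjusted p of Krt5 ranged from 8.41e-04 to 0.872, the highest without control 3, and this highest value was shared by the other genes that the naming rule took and that are given with a weighted p.

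The epithelial list was lower in mutants, with 12 of 16 members below 0 and a mean log2 change of -0.57 (camera adjusted p = 9.03e-06, and adjusted p = 0.253 with an estimated correlation). Over all genes 0 members passed, 5 passed adjusted over the list alone, and 7 fell with array weights. Krt5 had a log2 change -1.64, SE 0.10 (limma adjusted p = 0.0711), and weighted -1.64, SE 0.079 (limma adjusted p = 8.41e-04). Krt19 had a log2 change -0.99, SE 0.086 (limma adjusted p = 0.229), and weighted -0.99, SE 0.063 (limma adjusted p = 0.00192). Krt8, another keratin of simple epithelia, was 70.0 ± 6.19 FPKM in controls and 40.6 ± 1.35 FPKM in mutants (SD, n = 3). Krt15, a keratin of basal cells, was 285 ± 12.5 FPKM in controls and 144 ± 28.1 FPKM in mutants (SD, n = 3). The weighted limma adjusted p was 0.0154 for Krt8 and 0.0201 for Krt15. Krt6a, which was in no list, was 21.5 ± 2.57 FPKM in controls and 7.47 ± 1.17 FPKM in mutants (SD, n = 3) (weighted limma adjusted p = 0.0103). For all of these keratins each mutant lay below each control. The list also held 8 adhesion and splicing genes of epithelia. Without mutant 1 these 8 had a median log2 change of -0.092 (interquartile range -0.30 to 0.12), so some of them were lower. The adhesion molecules Epcam and Cdh1, which are among the 8, were not lower. Epcam was 18.5 ± 5.02 FPKM in controls and 21.5 ± 4.98 FPKM in mutants (SD, n = 3). Cdh1 was 19 ± 2.27 and 22.8 ± 4.19 FPKM (SD, n = 3).

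**Figure D2:**
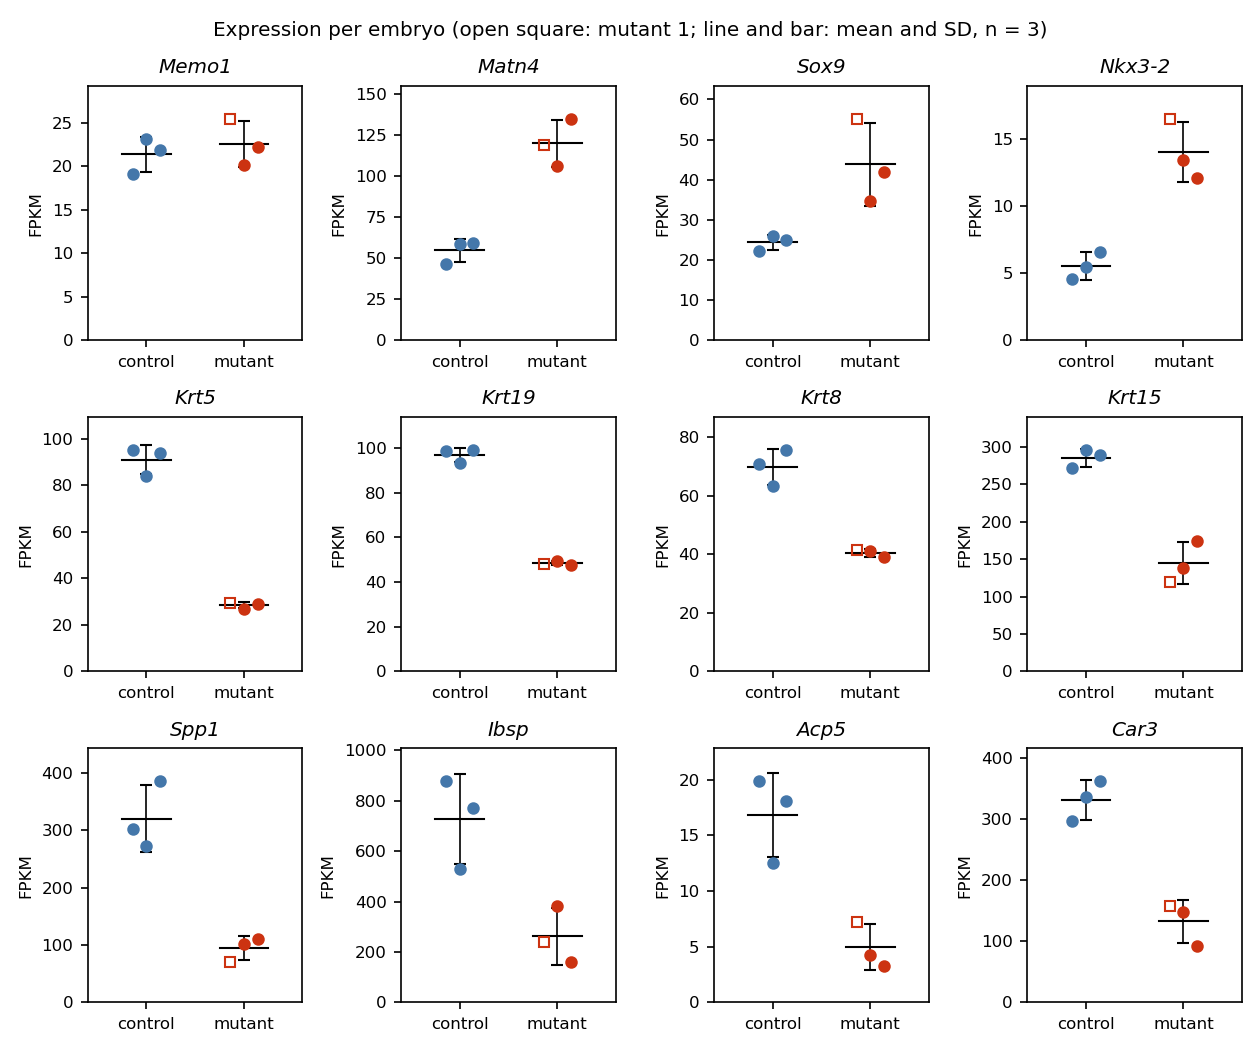
FPKM of 12 genes in each embryo (y axis, linear from 0), controls left and Memo1 mutants right, with the mean and SD of 3 embryos and mutant 1 as an open square. Memo1 overlaps between genotypes, while for the other 11 genes each mutant lies on one side of all 3 controls.

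Cartilage genes were higher in mutants. Of 24 genes of cartilage matrix and chondrocyte identity 21 were above 0, the mean log2 change was 0.37 (camera adjusted p = 3.32e-11, and adjusted p = 0.287 with an estimated correlation), and in 16 of them every mutant lay above every control. Over all genes 0 passed, 13 passed adjusted over the list alone, and 6 rose with array weights. Sox9, the transcription factor that sets chondrocyte fate, was 24.4 ± 1.9 FPKM in controls and 43.9 ± 10.3 FPKM in mutants (SD, n = 3) (weighted limma adjusted p = 0.0332). Matn4 had a log2 change 1.11, SE 0.15 (limma adjusted p = 0.608), and weighted 1.17, SE 0.13 (limma adjusted p = 0.0164). Lect1, the cartilage glycoprotein chondromodulin, was 582 ± 36.1 FPKM in controls and 810.2 ± 79.6 FPKM in mutants (SD, n = 3) (weighted limma adjusted p = 0.0352). Col2a1, the main cartilage collagen, was 1847 ± 327 FPKM in controls and 2486 ± 172 FPKM in mutants (SD, n = 3). Nkx3-2, a transcription factor of early chondrocytes, was 5.53 ± 1.02 FPKM in controls and 14 ± 2.24 FPKM in mutants (SD, n = 3) (weighted limma adjusted p = 0.0223). Other genes with the smallest p among the higher ones were Zic1, a transcription factor, at 16.7 ± 3.7 FPKM in controls and 36.8 ± 4.2 FPKM in mutants (SD, n = 3), and 2 matrix genes. Fbln2 was 66.6 ± 0.897 FPKM in controls and 96.7 ± 7.41 FPKM in mutants (SD, n = 3). Tgfbi was 63.9 ± 1.72 FPKM in controls and 90.1 ± 3.95 FPKM in mutants (SD, n = 3). Their weighted limma adjusted p were 0.0348, 0.0125 and 0.0234. None of the 8 higher genes with the smallest p, which include Lyz2, Arsi and Gm6969, passed with equal weights (limma adjusted p from 0.608 to 0.695). The 8 lower ones, which include Aldh1a1, did not either (limma adjusted p from 0.0711 to 0.666).

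Bone genes were lower in mutants. Of 25 genes of osteoblasts and mineralization 22 were below 0, with a mean log2 change of -0.70 (camera adjusted p = 7.47e-08, and adjusted p = 0.33 with an estimated correlation). None passed over all genes, 4 passed adjusted over the list alone, and 4 fell with array weights. Spp1 had a log2 change -1.76, SE 0.21 (limma adjusted p = 0.566), and weighted -1.53, SE 0.13 (limma adjusted p = 0.00929). Ibsp, the matrix protein bone sialoprotein, was 727 ± 177 FPKM in controls and 262 ± 112 FPKM in mutants (SD, n = 3) (weighted limma adjusted p = 0.0674). Dmp1, a matrix protein of osteocytes, was 15.7 ± 2.94 FPKM in controls and 5.02 ± 1.89 FPKM in mutants (SD, n = 3) (weighted limma adjusted p = 0.0223). Mmp13, the collagenase of terminal chondrocytes and osteoblasts, was 27, 19 and 33.3 FPKM in the controls and 0, 1.28 and 1.19 FPKM in mutants 1, 2 and 3 (weighted limma adjusted p = 0.00159). The hypertrophic chondrocyte list did not pass with all 6 libraries (mean log2 change -0.42, camera adjusted p = 0.202), and 5 of its 18 members passed adjusted over the list alone. With array weights it passed (mean log2 change -0.44, camera adjusted p = 0.0271, and adjusted p = 0.401 with an estimated correlation). Without members that other lists share, 6 of them with the bone list, its direction turned (mean log2 change 0.015, camera adjusted p = 0.625). Its collagen Col10a1 was 383 ± 68 FPKM in controls and 403 ± 25.9 FPKM in mutants (SD, n = 3).

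The osteoclast genes did not move as 1 group. The list of 12 did not pass (mean log2 change -0.37, median -0.024, camera adjusted p = 0.216), but 3 members passed adjusted over the list alone, all lower. Of 20 settings with a preset correlation it passed in 1, without a filter on low values (mean log2 change -0.41, camera adjusted p = 7.26e-04, and adjusted p = 0.134 with an estimated correlation), and the highest camera adjusted p was 0.981 at 20 FPKM, where the direction of the test turned. By fry the adjusted p was 0.0686 with all 6 libraries, 0.00562 with array weights and 0.0239 without mutant 1. Mmp9, the gelatinase of osteoclasts, was 25.6 ± 5.98 FPKM in controls and 5.31 ± 0.806 FPKM in mutants (SD, n = 3). Acp5, their acid phosphatase, was 16.8 ± 3.8 FPKM in controls and 4.95 ± 2.06 FPKM in mutants (SD, n = 3). Ctsk, the protease cathepsin K, was 72.6 ± 11.9 FPKM in controls and 37.3 ± 6.07 FPKM in mutants (SD, n = 3). With array weights the 3 fell over all genes too (limma adjusted p = 0.0103, 0.0125 and 0.0475). Tcirg1, a proton pump subunit also made elsewhere, was 19 ± 1.95 FPKM in controls and 25.5 ± 6.87 FPKM in mutants (SD, n = 3).

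Fat cell genes were lower in mutants, with all 10 members of the list below 0 and a mean log2 change of -1.45 (camera adjusted p = 5.77e-10, and adjusted p = 0.287 with an estimated correlation). Over all genes 0 passed, 5 passed adjusted over the list alone, and 6 fell with array weights. Car3, a carbonic anhydrase abundant in fat and muscle, was 332 ± 32.6 FPKM in controls and 133 ± 34.9 FPKM in mutants (SD, n = 3) (weighted limma adjusted p = 0.0159). Adipoq, the fat cell hormone adiponectin, was 22, 30.7 and 29.1 FPKM in the controls and 0, 6.66 and 3.93 FPKM in mutants 1, 2 and 3. Cidec, a lipid droplet protein, was 3.29, 3.56 and 3.39 FPKM in the controls and 0, 0.22 and 0.289 FPKM in mutants 1, 2 and 3 (weighted limma adjusted p = 0.0125 for Adipoq and 0.00438 for Cidec). Skeletal muscle genes were lower as well, with 11 of 17 below 0 and a mean log2 change of -0.24 (camera adjusted p = 0.0154, and adjusted p = 0.656 with an estimated correlation). This call was lost without control 3 (mean log2 change -0.11, camera adjusted p = 0.262) and without mutant 3 (mean log2 change -0.13, camera adjusted p = 0.55). It was lost with embryo sex as a covariate too (mean log2 change -0.13, camera adjusted p = 0.561), which takes mutant 3, the only female, out of the contrast, and without a filter on low values (camera adjusted p = 0.0619). No muscle gene passed over all genes or adjusted over the list alone. Ckm, muscle creatine kinase, was 361 ± 103 FPKM in controls and 215 ± 29.5 FPKM in mutants (SD, n = 3).

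Another 6 lists were higher in mutants by smaller amounts. The genes of hypoxia and glycolysis had 16 of 21 members above 0 and a mean log2 change of 0.19 (camera adjusted p = 4.01e-04, and adjusted p = 0.33 with an estimated correlation). The endothelial genes had 15 of 17 members above 0 and a mean log2 change of 0.19 (camera adjusted p = 0.0018, and adjusted p = 0.309 with an estimated correlation). The genes of BMP and TGF-beta signalling had 18 of 25 members above 0 and a mean log2 change of 0.16 (camera adjusted p = 0.00186, and adjusted p = 0.253 with an estimated correlation). The Hedgehog pathway genes had 11 of 13 members above 0 and a mean log2 change of 0.26 (camera adjusted p = 0.00398, and adjusted p = 0.299 with an estimated correlation). The genes of FGF and ERBB signalling had 18 of 24 members above 0 and a mean log2 change of 0.18 (camera adjusted p = 0.00398, and adjusted p = 0.309 with an estimated correlation). The pericyte and smooth muscle genes had 7 of 10 members above 0 and a mean log2 change of 0.14 (camera adjusted p = 0.0154, and adjusted p = 0.33 with an estimated correlation). Over all genes no member of any of the 6 passed, and adjusted over the list alone 2 passed in the BMP and TGF-beta list and 1 in the pericyte list. Cyr61, a matrix protein induced by growth factors, was 31.8 ± 0.99 FPKM in controls and 45.6 ± 1.22 FPKM in mutants (SD, n = 3). Gdf10, a BMP family ligand, was 50.8 ± 3.13 FPKM in controls and 84.8 ± 21.5 FPKM in mutants (SD, n = 3). Cspg4, a proteoglycan of pericytes, was 13.7 ± 0.598 FPKM in controls and 20.5 ± 0.505 FPKM in mutants (SD, n = 3). Their weighted limma adjusted p were 0.0223, 0.0125 and 0.0245. Fgfr3, a growth factor receptor of chondrocytes that stood in the cartilage and the FGF list, was 48.4 ± 6.69 FPKM in controls and 74 ± 15.1 FPKM in mutants (SD, n = 3). Ihh, the Hedgehog ligand of cartilage, was 17.9 ± 2.6 FPKM in controls and 26.5 ± 4.23 FPKM in mutants (SD, n = 3). With array weights neither passed (limma adjusted p = 0.075 and 0.202). The hypoxia call was lost without mutant 2 (mean log2 change 0.077, camera adjusted p = 0.0915) and with the title word as a fixed block (mean log2 change 0.077, camera adjusted p = 0.0561). That block takes mutant 2, the only embryo with its title word, out of the contrast, so these losses are not separate. The BMP and TGF-beta call was lost without mutant 3 (mean log2 change 0.11, camera adjusted p = 0.0696). The pericyte call was lost without control 1 (mean log2 change 0.048, camera adjusted p = 0.126) or mutant 3 (mean log2 change 0.022, camera adjusted p = 0.205), and its mean log2 change was 0.21 without control 2 and 0.27 without mutant 1. With sex as a covariate the BMP call (mean log2 change 0.11, camera adjusted p = 0.0686) and the pericyte call (mean log2 change 0.022, camera adjusted p = 0.20) were lost as well. With a filter of 20 FPKM, chosen after seeing the data, the pericyte call (mean log2 change 0.26, camera adjusted p = 0.325) and the Hedgehog call (mean log2 change 0.20, camera adjusted p = 0.194) were lost, and with a pseudocount of 0.1 the pericyte mean was below 0 (mean log2 change -0.023), although the test direction stayed higher.

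The other lists did not pass with all 6 libraries. Mean log2 changes were -0.21 for macrophage and microglia, -0.092 for neutrophil and mast cell, -0.013 for erythroid, 0.17 for neuron, -0.11 for glia and Schwann cell, -0.28 for pituitary and hypothalamus, -0.998 for inner ear, -0.14 for tendon or ligament and fibroblast, -0.10 for cell cycle, -0.030 for Wnt pathway, 0.090 for IGF and insulin pathway, -0.41 for matrix proteases and inhibitors, -0.13 for immediate-early and heat-shock, 0.0034 for unfolded protein and amino acid response, -0.31 for oxidative stress and metal response and -0.17 for interferon and p53 response, with camera adjusted p from 0.134 to 0.966. For matrix proteases the mean and the median (0.13) differed in sign, with Mmp13 and Mmp9 lowest. The Wnt list had a mean below 0, a median of 0.050 and a test direction of higher, and the immediate-early list a mean and median (-0.047) below 0 and a test direction of higher. The neuron list passed without control 1 (mean log2 change 0.34, camera adjusted p = 0.00179, and adjusted p = 0.432 with an estimated correlation) and the pituitary list without mutant 2 (mean log2 change -1.07, camera adjusted p = 0.037, and adjusted p = 0.716 with an estimated correlation). The inner ear list passed without control 1 (mean log2 change -1.34, camera adjusted p = 0.0403, and adjusted p = 0.467 with an estimated correlation) or control 3 (mean log2 change -1.43, camera adjusted p = 0.0304, and adjusted p = 0.49 with an estimated correlation). The inner ear mean rested on control 2, without which it was -0.22 (camera adjusted p = 0.687). With array weights the macrophage list was lower (mean log2 change -0.21, camera adjusted p = 0.00192, and adjusted p = 0.225 with an estimated correlation), and it passed in 3 of 20 settings with a preset correlation, although Lyz2, a lysozyme of macrophages and neutrophils, was 44.1 ± 3.4 FPKM in controls and 70.6 ± 0.404 FPKM in mutants (SD, n = 3). Cell cycle genes were lower with array weights too (mean log2 change -0.16, camera adjusted p = 3.39e-04, and adjusted p = 0.269 with an estimated correlation) and passed in 5 of 20 such settings.

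**Figure D3:**
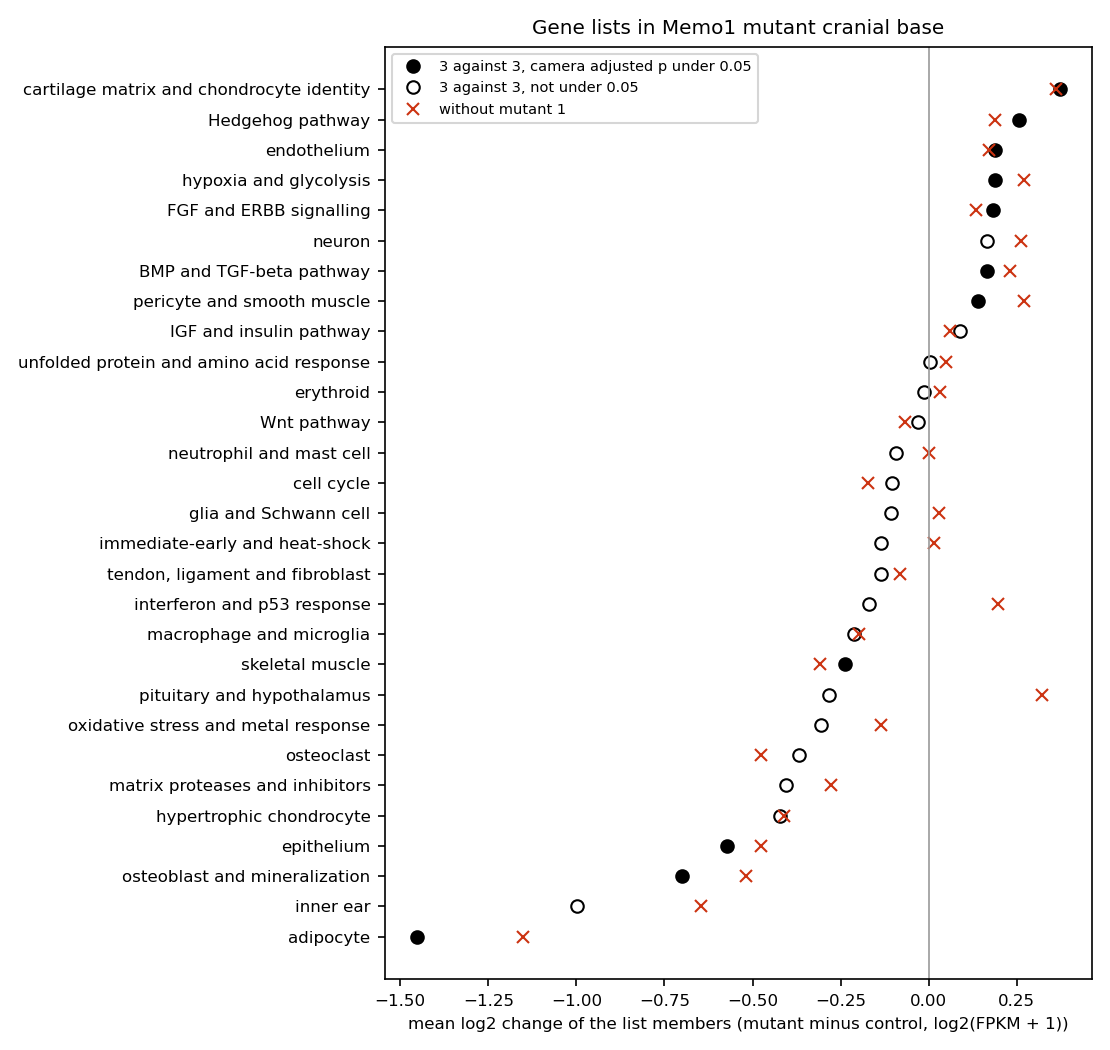
Mean log2 change of the members of each of 29 gene lists (x axis, mutant minus control on log2(FPKM + 1)), with all 6 libraries as circles, filled where the camera adjusted p was under 0.05, and without mutant 1 as crosses. Fat cell, bone and epithelial lists lie below 0 and the cartilage list above 0 with and without mutant 1, while 6 lists that did not pass, among them the interferon and p53 list and the pituitary list, change sign.

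The call of 11 lists was made with a preset correlation between genes of 0.01. With the correlation estimated from the 6 libraries 0 lists passed, and fry, which tests whether the genes of a list move one way and not whether they differ from other genes, passed 2, the epithelial list (adjusted p = 0.0227) and the fat cell list (adjusted p = 0.0329). Both fry calls were lost in some alternatives. The epithelial one was lost with the title word as a fixed block (fry adjusted p = 0.0653). The fat cell one was lost with a pseudocount of 0.1 (fry adjusted p = 0.0597) and a filter of 5 FPKM (fry adjusted p = 0.0658).

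The authors' deposited table gave q under 0.05 for 3 genes. In the authors' deposited table Krt19 had a signed fold of -2 with q = 0.0286, Krt5 a signed fold of -3.2 with q = 0.0332, and Ext2, an enzyme of heparan sulfate synthesis, a fold of 1.16 with q = 0.0332. There were 5 genes with q under 0.1 in the authors' deposited table, the other two being Cyr61, at a fold of 1.43, and the pseudogene Rpl3-ps1, at a signed fold of -1.18, both with q = 0.0941. The authors' deposited table listed 1427 genes at p under 0.05.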

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

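The filter of 20 FPKM was chosen after seeing the data, all other settings before. The count of genes at an adjusted p of 0.05 was 0 in the test of all 6 libraries, 1 with quantile normalization (Gpd1), 1 at 20 FPKM (Krt5), 320 with array weights and 0 in the other settings that kept all libraries, and it ranged from 0 to 7 with 1 library left out, the highest without mutant 1, which gives fewer samples but takes out the library with the most zeros. The count at an unadjusted p under 0.05 was 805, 1237 without a filter (more genes tested), 391 at 20 FPKM (fewer genes tested), 2876 with array weights and 322 to 2666 with 1 library left out. The number of lists past the threshold was 11, 8 to 14 in the other settings with a preset correlation, 0 with the estimated correlation and 2 with fry. Cartilage, bone, fat cell, epithelial, endothelial and FGF lists passed in every setting with a preset correlation in which they were tested, the fat cell list having too few members at 20 FPKM. Of 20 such settings the Hedgehog list passed in 19, the hypoxia and BMP lists in 18 each and the muscle and pericyte lists in 16 each. The eBayes settings do not enter a list test and only repeated its main values. The sex covariate takes mutant 3 out of the contrast, as leaving it out does. These counts thus hold settings that are not separate checks. The Memo1 log2 change was 0.074, -0.0069 with quantile normalization and -0.011 to 0.15 with 1 library left out, below 0 without control 1 (-2.5e-04) and without mutant 1 (-0.011), and never past the threshold. For other named genes and lists the direction turned as follows, the value being the log2 change or the mean over the list, with the direction of a list taken from its test, which can differ from the sign of its mean. Shared members left out: hypertrophic chondrocyte 0.015, glia and Schwann cell -0.095, matrix proteases and inhibitors -0.071. Mean of at least 20 FPKM: osteoclast -0.10, matrix proteases and inhibitors -0.33. Embryo sex as a covariate: neutrophil and mast cell 0.038, erythroid -0.039. Pseudocount 0.1: erythroid -0.16, matrix proteases and inhibitors -0.57. Mean of at least 5 FPKM: erythroid 0.16. Upper-quartile scaling: glia and Schwann cell -0.14. Quantile normalization: glia and Schwann cell 0.0071, Wnt pathway -0.0038, interferon and p53 response 0.024, Six3 0.087, Usp18 0.078. Median-ratio scaling: glia and Schwann cell -0.15. Title word as a fixed block: glia and Schwann cell -0.13, matrix proteases and inhibitors -0.43, immediate-early and heat-shock -0.22. Array weights: glia and Schwann cell 0.038, matrix proteases and inhibitors -0.27, interferon and p53 response 0.17, Pitx1 0.15, Dfna5 0.11, Bst2 0.34, Usp18 0.037. Fry: Wnt pathway -0.030. No filter on low values: matrix proteases and inhibitors -0.35, interferon and p53 response -0.14. With 1 library left out the ranges were neutrophil and mast cell -0.32 to 0.14, erythroid -0.073 to 0.073, neuron -0.11 to 0.34, glia and Schwann cell -0.21 to 0.028, pituitary and hypothalamus -1.07 to 0.39, tendon, ligament and fibroblast -0.19 to -0.083, Wnt pathway -0.068 to 0.0027, matrix proteases and inhibitors -0.48 to -0.28, immediate-early and heat-shock -0.26 to 0.015, interferon and p53 response -0.39 to 0.20, Pitx1 -0.63 to 0.26, Dfna5 -0.88 to 0.11, Bst2 -2.10 to 0.44, Usp18 -0.70 to 0.060. Of all values that turned, only the interferon and p53 list without mutant 1 was past the threshold (mean log2 change 0.20, camera adjusted p = 0.0248, and adjusted p = 0.369 with an estimated correlation and 0.108 with fry). The causes were not tested. Of the genes that turned, Six3 was 1.0, 2.16 and 0.512 FPKM in the controls and 0, 2.38 and 0.267 FPKM in mutants 1, 2 and 3, Dfna5 was 2.54, 2.57 and 2.29 FPKM in the controls and 0, 2.55 and 2.94 FPKM in mutants 1, 2 and 3, Bst2 was 19.8, 21.7 and 21.4 FPKM in the controls and 0, 32.8 and 25.2 FPKM in mutants 1, 2 and 3 and Usp18 was 1.43, 1.25 and 2.08 FPKM in the controls and 0, 1.86 and 1.49 FPKM in mutants 1, 2 and 3. Of the other comparisons of named genes and lists with their alternatives, 2264 and 542 kept direction and side of the threshold. The 542 of lists include the eBayes settings, which could not differ. Embryos that share a title word deviated from their group means with r from 0.0061 to 0.044 across genes. As a fixed block the word takes mutant 2, the only embryo with its word, out of the contrast. This block left 0 genes called and ended, among the camera calls of lists, that of hypoxia alone (camera adjusted p = 0.0561). By fry it ended the epithelial call too (adjusted p = 0.0653). List tests were not run with the random effect, which camera does not take. Zeros limit what can be said of low genes in mutant 1, where 22.6% of genes at 5 to 10 FPKM were listed at 0, against 4.84% at 20 to 50 FPKM. Of the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, 10 gave as many genes as the real 0 (highest other 0), 1 gave as many as the real 320 with array weights (highest other 7), and 1 gave as many lists as the real 11 (highest other 6); the split test of the first count was chosen after that count was seen.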

Other observations

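The tests of depth, sex and other tissues for bone, osteoclast and fat cell genes, of a lower epithelial share and of sex for epithelial genes, and of the title word for mutant 1 were chosen after the results they bear on were seen. The other tests were written down before their values were seen.

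A list of motile cilia genes was lower in mutants. The list of 20 such genes was written after the first fits and before any of its values were seen, and stands outside the 29 fixed lists. Of 16 members tested, 16 were below 0 without mutant 1, with a median log2 change of -0.85 (camera p = 1.93e-11, and p = 0.131 with an estimated correlation). With all 6 libraries the median was -0.92 (camera p = 7.4e-10, and p = 0.0468 with an estimated correlation), and 0 members passed over all genes. With array weights it was -0.85 (camera p = 8.59e-13, and p = 0.0848 with an estimated correlation). These p are not adjusted over lists, unlike those of the fixed lists. By camera with an estimated correlation and all 6 libraries, the epithelial list had an unadjusted p = 0.013 and an adjusted p = 0.253. Tppp3, the most abundant member, was 230.4, 185 and 264 FPKM in the controls and 141, 145 and 138 FPKM in mutants 1, 2 and 3 (weighted limma adjusted p = 0.0558). With array weights 6 members fell at an adjusted p of 0.05 over all genes. Rsph1, a radial spoke protein, was 48.1, 32.5 and 43.3 FPKM in the controls and 26, 19.9 and 18.3 FPKM in mutants 1, 2 and 3 (weighted limma adjusted p = 0.0279). Sntn, a protein of cilia tips, was 2.13, 1.23 and 2.58 FPKM in the controls and 0, 0.106 and 0.122 FPKM in mutants 1, 2 and 3 (weighted limma adjusted p = 0.0343). Foxj1, the transcription factor of the ciliary programme, was 64.1, 50.4 and 66.7 FPKM in the controls and 75.7, 53.8 and 49.8 FPKM in mutants 1, 2 and 3 and did not pass (weighted limma adjusted p = 0.428). Over the alternatives the weighted value was the lowest limma adjusted p of these 4 genes, and the highest was 0.981 for Foxj1, without control 1, and 0.872 for each of the others, without control 3.

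Hox genes of paralogue groups 1 to 5, which mark position from the hindbrain backwards, were mostly higher: 11 of 13 were above 0 without mutant 1, and Hoxa2 was 6.34, 7.27 and 7.56 FPKM in the controls and 11.3, 10.6 and 11.5 FPKM in mutants 1, 2 and 3. Genes of neighbouring tissues differed between single libraries. The pituitary hormone gene Pomc was 1.71, 53.7 and 1.53 FPKM in the controls and 0, 66.2 and 2.44 FPKM in mutants 1, 2 and 3, high in control 2 and mutant 2. The otoconia gene Oc90 of the inner ear was 0.16, 53 and 0.075 FPKM in the controls and 0, 0 and 0.0461 FPKM in mutants 1, 2 and 3, high in control 2 alone.

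Ciliated-cell genes had a median log2 change of -0.85 without mutant 1, the result set beforehand for fewer ciliated epithelial cells. But the change of Foxj1, which these cells need, was only -0.21. Krt5 and Krt15 are keratins of basal cells, so fewer ciliated cells need not account for their falls. A lower share of all epithelial cells was tested with 8 adhesion and splicing genes of epithelia and stays open. Without mutant 1 their median log2 change was -0.092 (interquartile range -0.30 to 0.12). Of the basal keratins Krt5 and Krt15, Krt15 fell less, at -0.87. The gap passed the bound set for it, the interquartile range of the 8 genes. But the 2 keratins were set against these genes after their falls were seen, so a gap was likely in any case. The values show only that the 8 genes did not fall as far as the keratins. Krt8, which was not part of that test, was at -0.79. The whole epithelial list had a median of -0.44, but these 8 genes are members of it. Embryo sex was not settled: in male mutants 1 and 2 against the male controls, the contrast that a sex covariate leaves, the list passed as lower (camera adjusted p = 0.00378, and adjusted p = 0.447 with an estimated correlation), but its 16 members had a median of -0.28 and an upper quartile of 0.046. In the deep male mutant 2 alone these were -0.39 and -0.089. Whether fewer such cells formed in mutants, fewer were dissected or each made less of these mRNAs stays open.

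Depth of mutant 1 is argued against for the bone and fat cell lists, whose members had upper quartiles of -0.16 and -0.64 without it, although with an estimated correlation neither list passed there (adjusted p = 0.393 and 0.368) and fry passed only the second (adjusted p = 0.17 and 0.0331). Sex as the whole cause is argued against for both, by male mutants 1 and 2 against the male controls, the contrast that a sex covariate leaves. There their upper quartiles were -0.17 and -1.12 and both lists passed (camera adjusted p = 3.16e-04 and 1.79e-06, and adjusted p = 0.654 and 0.447 with an estimated correlation). In mutant 2 alone the upper quartiles were -0.017 and -0.54, and the bone median was only -0.23. For bone genes this test thus leans on mutant 1, and sex and depth acting together stay open. For the osteoclast list depth and sex stay open: without mutant 1 its mean was -0.48 and fry passed it (adjusted p = 0.0239), but its median was -0.087, its upper quartile 0.062 and camera did not pass it (adjusted p = 0.0695, and 0.368 with an estimated correlation), and in male mutants 1 and 2 the upper quartile was 0.17. Whether every other tissue had a smaller share was asked of 5 other tissue lists, and 3 met the bar of 3. For neurons, endothelium and pericytes the lower quartile lay above the upper quartiles of the bone and fat cell lists without mutant 1. Muscle, with a median of -0.37, and tendon, with a median of -0.057 and a lower quartile of -0.43, did not. Without control 3 the neuron mean turned to -0.11. The endothelial mean stayed at 0.15 to 0.22 with any 1 library left out. Endothelial genes thus argue against an equal loss of every other tissue, although their list did not pass with an estimated correlation. A loss of some of these tissues stays open. Another level of dissection along the head cannot be told apart from an effect of genotype: the median of the Hox genes was 0.63, past the 0.5 set for it, but not all of them went one way, so both stay open.

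Mutant 1 may stand apart because few of its fragments were sequenced: among genes at 2 to 10 FPKM the shortest genes (1 of 3 equal parts by exon length) were listed at 0 4.15 times as often as the longest (59.9% against 14.4%). The title word shared with control 1 is argued against, since control 1 had a median r of 0.976 with the other 4 libraries. Another tissue or a wrong label was not excluded: over genes of at least 50 FPKM its r with the mean of the other 5 was 0.648, under the 0.8 set for that case, though few fragments lower r too. In the 10% of genes with the most expected fragments r was 0.874, between the 0.8 and 0.9 set as bounds, against at least 0.984 for each other library.

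Whether one change was seen in separate embryos was tested by setting the log2 change of mutant 1 over control 1 against that of mutants 2 and 3 over controls 2 and 3, which share no library. Across 1979 genes of at least 50 FPKM, which are not independent replicates, r was 0.165 (Spearman's rho 0.261), between the 0.05 and 0.2 set as bounds, so this test did not decide. Whether genes beside Memo1 differ because they came with the mutated chromosome was not decided either. The median absolute t of the 100 nearest tested genes was 1.19, at percentile 73.5 of 10000 random lists matched on mean expression, whose median was 1.11. The bound of 95 set beforehand to exclude it was too weak, since the value lay above the random median and a small effect need not reach that bound. For this the annotation gave only the order of genes.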
